A study of Homo sapiens with 16 samples.

How the data were processed

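The series holds 16 two-colour microarrays of the human embryonic stem cell lines H1 and H13. Undifferentiated cells (D0) were compared with the same line after 21 days (D21) or 90 days (D90) of undirected differentiation. Each line and stage has 2 biological replicates, A and B, for gene expression and for DNA methylation, so each assay has 8 arrays in 4 groups. Per the labels, the undifferentiated sample was labelled with Cy3 and the differentiated sample with Cy5 on every array. No array swaps the dyes, so the dye cannot be told apart from the stage in a comparison with D0, while a gene's dye effect cancels in D90 against D21 and in H13 against H1.

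Per the labels' protocols, the methylation assay cut the DNA with SmaI, which cuts only unmethylated CCCGGG sites, and then with XmaI, which also cuts methylated ones. Adaptors were ligated to the XmaI ends and the fragments were amplified by PCR. A higher ratio on these arrays therefore stands for more methylated fragment ends in the differentiated cells.

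Per the submitters' processing notes, the arrays were read with Agilent Feature Extraction 9.1.3.1. Per the file headers, the mean and local background values are spot intensities in each channel with no normalization. Per the file headers, the processed signals are intensities after detrending and dye normalization, linear with LOWESS for expression and linear alone for methylation. The LogRatio column holds the log10 of the Cy5 over the Cy3 processed signal, per the file headers. The deposited value tables hold the same log10 ratios, to within 0.005. The flag columns, which are neither ratios nor signals but other marks of saturated, uneven or dim spots, come per the file headers from the same software.

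Expression was computed from the mean and background intensities by normexp background correction with an offset of 50 and loess within each array. A probe was tested if it was well above background in either channel on at least 2 of the 8 arrays. Symbols were updated by accession for 23958 probes, by current symbol for 2755 and by an older symbol for 1032, and 13255 probes had none. Current symbols covered 17843 genes. Each gene was represented by its probe with the highest average intensity. A gene saturated on every array of a line is given as a bound, which is open to dye bias. Some named genes were well above background on only some arrays of a group. At D0 on the 4 D21 arrays these were RUNX2 (1), ALDH1A1 (2), and ERG, HOXD10, TET2, SLITRK6, ZBED2, NELL1 and PDE8B (3), and on the 4 D90 arrays SLITRK6, ZBED2 and SST (2), and CCL4 and PAX6 (3). In the differentiated channel they were TTN and SOHLH2 at D21 and CRHBP at D90 (3). CDKN2B and PLAGL1 have a value on 3 of the 4 D21 arrays, since flagged outlier spots were left out.

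Methylation was computed from the processed signals as a log2 ratio centred on each array's median of the measured spots. A spot whose signal was replaced by a surrogate in both channels kept a ratio of 0. The 224313 probes were joined into runs with gaps of at most 500 bp, and 49824 runs held at least 2 probes. A region was tested if at least 50% of its probes were well above background in either channel on at least 2 arrays, which left 31058 regions. The methylation files give positions without a genome build and without gene names. The positions run past chromosome ends of the reference that came with the names, so its annotation could not be laid over them, and no table of an older build was at hand. A methylation probe was given a gene's name where it shares at least 30 bases with an expression probe of 1 gene on the same chromosome. This named 658 probes of 608 genes, and 465 tested regions carry a name. Expression probes lie in transcribed sequence, and whether these regions also cover promoters is not known. The plan had joined regions to genes by symbols of the methylation array, which the files do not hold. The comparison of the assays and the gene lists for methylation use the named regions in their place.

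For each assay, limma fitted the 4 group means over all 8 arrays, and contrasts gave D21 and D90 against D0, D90 against D21, and H13 against H1 at each stage. The last of these is the interaction of line and differentiation, since every value is a ratio to D0 of the same line. A group contributes 2 arrays, so residual degrees of freedom were 4, with prior degrees of freedom of 3.06 for expression and 1.88 for methylation. Adjusted p-values are Benjamini-Hochberg values over the tested probes or regions, with a threshold of 0.05, and are called adjusted p throughout. Genes or regions past it are said to rise, fall or be called.

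20 gene lists of 20 to 89 genes were tested with limma's camera at a preset correlation of 0.01, which compares a list with all other genes, and again with an estimated correlation. Over the 5 contrasts, 24 of the 100 list tests were called, and 0 with an estimated correlation. At an unadjusted p under 0.05, 4 tests passed with an estimated correlation, those of the pluripotency and HOX lists at D21 and D90 against D0. Methylation and expression were compared by Spearman correlation across genes, with 100000 permutations, and Fisher's exact test.

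The named genes are the 10 with the largest rise and the 10 with the largest fall in each contrast among those called with the same sign on every array, and up to 4 members of each list with the smallest p plus members that moved against their list. They also include the genes called in both assays with the largest product of changes, and POU5F1, NANOG, SOX2, DNMT3B, AFP and COL1A1 as checks of the labels. Some genes that meet the rule are not reported here. Regions without a gene name are given as the 10 largest in each direction and were chosen after their values were seen. The contrasts, tests, gene lists, rule for named genes and alternatives were fixed before the data were examined, apart from those said to be chosen after the result was seen.

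The letters A and B were checked as pairs. Within a line, the difference between A and B on the D21 arrays correlated with that on the D90 arrays at 0.397 in H1 and 0.37 in H13 for expression, and at 0.558 and 0.668 for methylation. All 4 pairs exceed 0.1, so the arrays were treated as paired by letter. The labels give the letters but do not state whether D0 samples were shared. A fit with line and letter as a block, in which the letters of H1 and of H13 are separate terms, is given beside a result where it changes a call or moves a count by more than 1.5 times. Only D90 against D21 compares stages within such pairs. Where the block fit is called the paired fit for another contrast, that contrast itself is not paired. In the other contrasts this block takes the spread between letters out of the error. Its counts can therefore be too high and its adjusted p too low there, so a call gained with it there is not counted as one. A random block of line and letter is the fairer check. Among 322 named gene results the random block gained 1 call, against 5 with this block.

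The limma fits, region means, the block and the list test were tested on simulated data. Among 37018 expression probes with 100 changed 2-fold, 99 were recovered at D21 against D0, 98 at D90 against D0, 93 at D90 against D21, 79 in H13 against H1 at D21 and 82 at D90. With a 1.5-fold change these were 92, 93, 61, 15 and 10 of 100. Among 31058 methylation regions, 92, 88, 84, 35 and 52 of 100 were recovered at 2-fold in the same order, and 62, 59, 31, 1 and 1 at 1.5-fold. False calls, 3 to 18 in each contrast, made up 3.05% to 8.61% of the calls and passed 5% in 5 of the 10 contrasts. For these rates all arrays and features were drawn independently, unlike the measured arrays of a line and letter. The rates need not hold for the measured arrays.

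Alternatives were Agilent's own ratio, median centring, quantile normalization, no offset, other filters, gene means, single probes, larger regions, blocks, array weights, the deposited tables, a 2-fold minimum, and leaving out each array. Removing a trend with GC content, treating spots dim in both channels as missing, and the list tests with median centring or quantile normalization were added after the data were seen. All arrays were used. The software was R 4.3.3 with limma 3.58.1, statmod 1.5.0 and data.table (1.17.8), and Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9.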

Results

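Gene expression and DNA methylation were measured by two-colour arrays in the human embryonic stem cell lines H1 and H13. Each array set cells after 21 or 90 days of undirected differentiation (D21, D90) against undifferentiated cells (D0) of the same line. Each of the 4 groups of line and stage had 2 arrays per assay, 16 arrays in all. On the expression arrays 72.5% to 77.6% of spots were well above background in the D0 channel and 85.3% to 90.6% in the differentiated channel. On the methylation arrays these shares were 53.8% to 60.5% and 49.3% to 62%. Replicate arrays of a group correlated at 0.931 to 0.987 for expression and at 0.494 to 0.616 for methylation. Their number, 2 per group, limits the precision. Changes are log2 ratios with the standard error (SE) of the fit. This SE comes from the spread between the arrays of each group and leaves out the difference between the lines.

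The comparison of D21 with D0 asks which genes change as pluripotent cells differentiate without directed signals. Genes of connective tissue matrix rose most. DCN (decorin) rose at least 208-fold and COL3A1 (type III collagen) at least 156-fold, both saturated on the H1 arrays at D21. LUM (lumican) rose by 7.69 ± 0.29 and TGFBI, a matrix protein induced by TGF-beta, by 6.67 ± 0.08 (SE, n = 4 arrays). LOX (a collagen crosslinking oxidase, 6.32 ± 0.08), CILP (a cartilage matrix protein, 6.31 ± 0.14), CDH11 (a mesenchymal cadherin, 6.24 ± 0.16), ITGA11 (a collagen receptor, 6.07 ± 0.06) and TGFB2 (a growth factor, 5.78 ± 0.17) followed. FAP, a protease of activated fibroblasts, rose at least 61.7-fold; at D0 it was not well above background on the D21 arrays, though it was on the D90 arrays. Genes of the undifferentiated state fell most, among them NANOG by −6.96 ± 0.09, DNMT3B (a de novo DNA methyltransferase) by −5.85 ± 0.07, CRIPTO (a NODAL co-receptor) by −5.72 ± 0.09 and L1TD1 (an RNA-binding protein of pluripotent cells) by −4.84 ± 0.08. The neuropeptide genes NTS (−6.14 ± 0.20) and NMU (−5.36 ± 0.10), and CFAP95 (−5.30 ± 0.05), VRTN (−5.18 ± 0.08) and LARP7 (−5.03 ± 0.08) fell too. The largest adjusted p was 5.14e-07 among these rises, for LUM, and 2.58e-07 among these falls, for NTS. The genes held as checks of the labels included POU5F1, which fell by −4.16 ± 0.07 (3 arrays with a value), SOX2, which fell by −2.95 ± 0.06, and COL1A1, which rose by 3.92 ± 0.09. AFP, a fetal liver protein, rose by 1.46 ± 0.53 with adjusted p = 0.0419 as a mean over both lines. For AFP, H13 minus H1 was −3.33 at D21 (not called), so the rise lay in H1 and AFP was not higher in H13 on average. Its call was lost without H1 replicate B (0.52, adjusted p = 0.118), H13 replicate A (1.48, adjusted p = 0.121) or H13 replicate B (1.44, adjusted p = 0.128), with Agilent's own ratio (1.49, adjusted p = 0.119), with the deposited ratios (1.49, adjusted p = 0.119) and without the normexp offset (1.54, adjusted p = 0.0596), and the rise was 2.40 without H1 replicate A. Other probes of some genes gave other values: the 4 LARP7 probes ranged from −5.03 to 0.32, the TGFB2 probes from 2.75 to 5.78, the CRIPTO probes from −5.72 to −2.60 and the SOX2 probes from −7.35 to −2.95. The 3 COL3A1 probes ranged from 5.54 to 7.33, so the bound given for COL3A1 holds for its probe of highest intensity, not for all 3.

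Of 17171 genes tested, 12818 (74.6%) were called at D21, 6869 higher and 5949 lower, and 4502 of these changed at least 2-fold. H1 and H13 tested apart gave 11362 and 11490 calls. Of the 9792 genes called in both lines, 9643 moved the same way. Centring on the median in place of loess raised the median of all genes by 0.36 at D21 and by 0.32 at D90, so changes are relative to the loess centre.

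The mesenchyme and matrix list rose and the pluripotency list fell nearly in full at D21. Of 40 mesenchyme genes 39 rose and 0 fell, with a median of 3.80; COL15A1, a basement membrane collagen, rose by 4.35 ± 0.04. The list's adjusted p was 1.65e-12, and adjusted p = 0.284 with an estimated correlation. Of 38 pluripotency genes 36 fell, with a median of −3.12 (adjusted p = 7.56e-15; adjusted p = 0.284 with an estimated correlation). USP44, a deubiquitinase, fell by −4.40 ± 0.05 and LIN28A, a blocker of let-7 processing, by −4.12 ± 0.06. All 40 cell cycle genes fell, with a median of −2.01 (adjusted p = 8.62e-12; adjusted p = 0.417 with an estimated correlation). The replication helicase genes MCM4 and MCM5 fell by −2.57 ± 0.10 and −2.43 ± 0.11, and the mitotic kinase AURKA by −1.48 ± 0.06. Of 20 cell cycle inhibitors 15 rose and 4 fell, among them CDKN2B (4.73 ± 0.20), CDKN1A (2.67 ± 0.07) and CDKN2A (2.61 ± 0.07). As a list they did not pass (adjusted p = 0.0773). They passed with the letter as a block (adjusted p = 0.034), which can make adjusted p too low against D0.

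Genes of body patterning and of several lineages also rose at D21. Of 35 HOX genes, which set position along the body axis, 28 rose and 1 fell (adjusted p = 9.84e-05; adjusted p = 0.271 with an estimated correlation). HOXB9 rose by 3.94 ± 0.10, HOXC9 by 3.88 ± 0.07, HOXB4 by 3.19 ± 0.05 and HOXD10 by 2.80 ± 0.06. Of 32 TGF-beta and BMP genes 25 rose and 4 fell (adjusted p = 0.000265; adjusted p = 0.284 with an estimated correlation). Those that rose included LTBP1, which tethers latent TGF-beta (3.56 ± 0.08), TGFB3 (3.13 ± 0.06) and TGFB1 (2.16 ± 0.05), and those that fell included the BMP target ID1 (−1.66 ± 0.13) and the receptor BMPR1A (−1.46 ± 0.05). Of 24 trophoblast genes 18 rose and 1 fell (adjusted p = 0.00604; adjusted p = 0.284 with an estimated correlation). EPAS1, a hypoxia-inducible factor, rose by 4.73 ± 0.20, TFPI2, a protease inhibitor, by 2.87 ± 0.09 and HSD3B1, a steroid enzyme, by 2.68 ± 0.13, while the placental hormone gene CSH1 fell by −1.08 ± 0.06. Of 29 cardiac muscle genes 21 rose and 4 fell (adjusted p = 0.0352; adjusted p = 0.417 with an estimated correlation). The regulators HAND2 (2.98 ± 0.06) and NKX2-5 (1.22 ± 0.06) and the sarcomere gene TNNT2 (2.94 ± 0.12) rose, while the sarcomere genes TNNI3 (−2.43 ± 0.07), ACTN2 (−1.13 ± 0.10) and TTN (−0.92 ± 0.10) fell. The calcium channel gene RYR2 was also called lower, though well above background on only 2 of 4 arrays at D0 and 1 of 4 at D21. Of 29 epithelial and epidermal genes 18 rose and 2 fell (adjusted p = 0.0297; adjusted p = 0.546 with an estimated correlation). The keratins KRT19 (2.71 ± 0.11) and KRT8 (2.16 ± 0.09) rose, and the adhesion gene EPCAM, also a marker of pluripotent cells, fell by −2.40 ± 0.20.

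Of 33 imprinted genes 20 rose and 6 fell at D21 (adjusted p = 0.035; adjusted p = 0.284 with an estimated correlation). The growth genes DLK1 (at least 37.8-fold, adjusted p = 2.97e-08, saturated in H1) and IGF2 (at least 18.3-fold, adjusted p = 3.35e-08, saturated in both lines) and the zinc finger gene PLAGL1 (3.88 ± 0.07) rose, and SNRPN (−1.79 ± 0.06), SNURF (−1.39 ± 0.05) and NNAT (−0.85 ± 0.06) fell. Of 23 genes of the DNA methylation machinery 15 fell and 5 rose (adjusted p = 0.0297; adjusted p = 0.417 with an estimated correlation). Besides DNMT3B, DNMT3L, a cofactor of de novo methylation, fell by −2.74 ± 0.07 and the helicase HELLS by −2.53 ± 0.07. The stress genes GADD45B (3.08 ± 0.12) and GADD45A (1.93 ± 0.11), the methyl-CpG binders ZBTB38 (1.74 ± 0.06) and MBD1 (0.56 ± 0.07), and TET2 (0.74 ± 0.07), which oxidises 5-methylcytosine, rose. The median of this list was −0.39 and turned to 0.02 with median centring, where its call was lost (adjusted p = 0.157). Median centring also ended the calls of the trophoblast list (adjusted p = 0.111), the cardiac list (adjusted p = 0.353), the epithelial list (adjusted p = 0.309) and the imprinted list (adjusted p = 0.147).

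The other lists did not pass at D21. Of 36 hepatic and endoderm genes 12 rose and 6 fell (adjusted p = 0.268), with GATA6, an endoderm regulator, at 3.98 ± 0.16, VTN (vitronectin) at 3.94 ± 0.08 and FOXA3 at −2.52 ± 0.05. Of 38 neural genes 11 rose and 17 fell (adjusted p = 0.356), with STMN2 at 3.87 ± 0.18, RBFOX3 at −1.76 ± 0.04 and OTX2 at −1.55 ± 0.04. Of 19 cartilage and bone genes 8 rose and 7 fell (adjusted p = 0.853), with RUNX2 at 1.68 ± 0.08, CNMD at −4.05 ± 0.08 and ALPL at −2.39 ± 0.04; the median (0.04) and mean (0.08) were above 0 and the test pointed down. Of 32 vascular and blood genes 13 rose and 1 fell (adjusted p = 0.144), with RUNX1 at 3.15 ± 0.11 and ERG at 2.70 ± 0.12. Of 28 Polycomb and chromatin genes 7 rose and 17 fell (adjusted p = 0.0811), with PHC2 at 2.88 ± 0.09 and JARID2 at −3.53 ± 0.08. Of 30 germline genes 6 rose and 11 fell (adjusted p = 0.271), with TEX14 at −3.28 ± 0.10 and SOHLH2 at −2.38 ± 0.07. Median centring called the germline list lower (adjusted p = 0.00581). Of 82 lineage transcription factors 33 rose and 18 fell (adjusted p = 0.456), with TBX2 at 3.58 ± 0.05, PITX1 at 3.34 ± 0.08 and EOMES at −3.27 ± 0.22. Of 39 WNT genes 21 rose and 13 fell (adjusted p = 0.268); DKK2, a WNT antagonist, was at 4.39 ± 0.09 and the receptor FZD5 at −3.93 ± 0.12. Of 25 hypoxia and glycolysis genes 13 rose and 8 fell (adjusted p = 0.452), with SLC16A3 at 3.54 ± 0.05, NDRG1 at 3.07 ± 0.08 and ENO2 at −2.05 ± 0.10. Adjusted over the list alone, 37 pluripotency genes fell, 9 hepatic genes rose and 5 fell, and the counts of the other lists at D21 were as given.

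**Figure D1:**
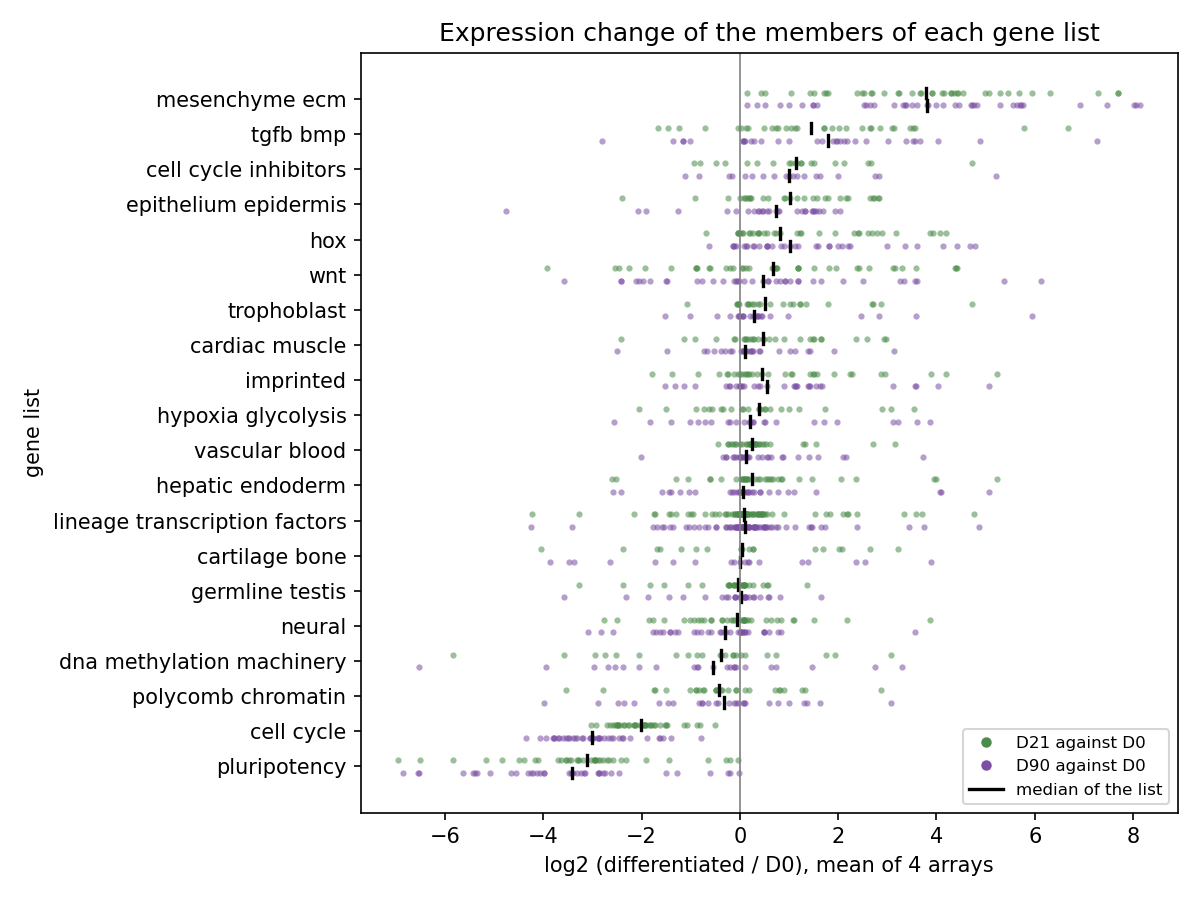
Members of each gene list (vertical axis) by log2 change against undifferentiated cells (horizontal axis), each point the mean of 4 arrays at D21 or D90 and each black line the median of a list. The mesenchyme list has medians of 3.80 and 3.82, and the pluripotency list of −3.12 and −3.43.

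At D90 matrix genes were again among the largest rises and pluripotency genes among the largest falls. Of the genes with a value on all 4 arrays, LUM was at 8.15 ± 0.29, DCN at 8.06 ± 0.09 (saturated on 1 H1 array), FAP at 8.03 ± 0.07 and LOX at 6.92 ± 0.08 (SE, n = 4). COL3A1 stood at least 178-fold and TGFBI at least 155-fold higher, both saturated on the H1 arrays. CDH11 (6.40 ± 0.16), SULF1, an editor of heparan sulfate (6.35 ± 0.11), IGFBP7, an IGF-binding protein (6.17 ± 0.10), and GDF6, a BMP-family ligand (6.16 ± 0.14, well above background at D0 in H1 alone), followed. ITGA11, with a value on 3 arrays, was at 7.46 ± 0.07. Those that fell most included NANOG (−6.86 ± 0.09), DNMT3B (−6.53 ± 0.07), NTS (−6.18 ± 0.20), CRIPTO (−5.96 ± 0.09), the FGF homolog FGF13 (−5.82 ± 0.16), PODXL, a surface sialomucin (−5.64 ± 0.27), MYCN (−5.44 ± 0.19), ZFP42 (−5.38 ± 0.13) and L1TD1 (−5.34 ± 0.08). The largest adjusted p among these genes was 1.17e-06 for PODXL. POU5F1 was at −4.22 ± 0.05, SOX2 at −2.87 ± 0.06 and COL1A1 at least 22-fold higher (adjusted p = 3.82e-08), saturated on the H1 arrays. AFP was at −0.91 ± 0.53 and did not pass (adjusted p = 0.159), but did with Agilent's own ratio (−3.28, adjusted p = 0.0069). AFP also passed with the letter as a block (adjusted p = 0.0304), which can make adjusted p too low against D0. Its D90 signal was well above background on 1 of 4 arrays, so these values and those of D90 against D21 rest on dim signals. The GDF6 probes ranged from 1.12 to 6.16, the MYCN probes from −5.44 to 0.41 and the SOX2 probes from −7.75 to −2.87. The 3 COL3A1 probes ranged from 5.64 to 7.63, so the bound for COL3A1 does not hold for all 3.

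Of 17170 genes tested, 13407 (78.1%) were called at D90, 7014 higher and 6393 lower, and 5119 changed at least 2-fold. Contrasts for H1 alone and H13 alone gave 11886 and 12277 calls, and 10161 of the 10307 genes called in both lines moved the same way. Calls at D21 and D90 shared 5915 higher and 5434 lower genes, and 189 had opposite signs. Independent lists of these sizes would share 2761.8 and 2197.1. Simulated unchanged groups with shared D0 samples shared 0, but few calls can arise without any change, so this 0 does not weigh the overlap. The changes correlated at 0.934 across genes (simulated 0.295), with a covariance of 1.26 (simulated 0.00246), and at 0.918 to 0.924 between stages of different letters. The simulated correlation only returns the 0.293 put in between arrays of a line and letter. No dye effect was simulated, so these correlations do not separate a shared change from a shared dye effect.

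At D90 the mesenchyme, HOX and TGF-beta lists were called higher, and the pluripotency, cell cycle and DNA methylation machinery lists lower. Again 39 of 40 mesenchyme genes rose, with a median of 3.82 (adjusted p = 2.76e-12; adjusted p = 0.381 with an estimated correlation), and 36 of 38 pluripotency genes fell, with a median of −3.43 (adjusted p = 1.5e-13; adjusted p = 0.349 with an estimated correlation). All 40 cell cycle genes fell, with a median of −3.01 (adjusted p = 1.86e-12; adjusted p = 0.451 with an estimated correlation); the replication licensing gene CDC6 was at −3.55 ± 0.11, MCM4 at −3.40 ± 0.10 and AURKA at −2.37 ± 0.06. Of 35 HOX genes 27 rose and 3 fell (adjusted p = 0.000139; adjusted p = 0.288 with an estimated correlation), with HOXC9 at 4.42 ± 0.07 and HOXB4 at 3.60 ± 0.05. Of 32 TGF-beta and BMP genes 22 rose and 5 fell (adjusted p = 0.00183; adjusted p = 0.381 with an estimated correlation). TGFB3 was at 3.67 ± 0.06, and among those that fell were BMP7 (−2.81 ± 0.20), ID1 (−1.36 ± 0.13) and BMP2 (−1.17 ± 0.10). Of 23 methylation machinery genes 15 fell and 5 rose, with a median of −0.55 (adjusted p = 0.0382; adjusted p = 0.451 with an estimated correlation), a call that median centring ended (median −0.30, adjusted p = 0.0932). HELLS was at −2.68 ± 0.07 and DNMT3L at −2.54 ± 0.07, against GADD45B at 3.30 ± 0.12 and ZBTB38 at 1.46 ± 0.06.

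The other 14 lists did not pass at D90. Rises and falls were 20 and 7 of 33 imprinted genes (adjusted p = 0.0628), which Agilent's own ratio called higher (adjusted p = 0.0464), and 7 and 21 of 38 neural genes (adjusted p = 0.0793), which median centring called lower (adjusted p = 0.00328). They were 13 and 3 of 19 cell cycle inhibitors, 16 and 4 of 29 epithelial genes, 13 and 4 of 24 trophoblast genes, 13 and 4 of 32 vascular genes, and 12 and 6 of 29 cardiac genes. They were 12 and 7 of 36 hepatic genes, 7 and 7 of 19 cartilage and bone genes, 7 and 15 of 28 Polycomb genes, 8 and 9 of 30 germline genes, 33 and 21 of 81 lineage transcription factors, 20 and 13 of 39 WNT genes, and 11 and 8 of 25 hypoxia genes. Adjusted over the list alone, 12 vascular, 6 methylation machinery and 21 WNT genes rose, with the other counts as given. The median was above 0 and the mean and test below it for cartilage and bone (0.01 and −0.28) and germline (0.02 and −0.23).

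The comparison of D90 with D21 asks what changes with longer culture. THBS2, a matrix thrombospondin, was higher at D90 by 4.44 ± 0.16, PTX3, an innate immune pentraxin, by 3.81 ± 0.16, ALDH1A1, an enzyme of retinoic acid synthesis, by 3.60 ± 0.17 and C1R, a complement protease, by 3.12 ± 0.16 (SE, n = 4 arrays per stage). IL13RA2, a decoy cytokine receptor (3.57 ± 0.13), the chemokine CXCL6 (3.02 ± 0.25), the matrix genes SMOC2 (2.86 ± 0.24), ASPN (2.71 ± 0.29) and EFEMP1 (2.64 ± 0.15), and DHRS3, a retinal reductase (2.63 ± 0.14), followed. The glutathione transferases GSTA2 (−4.04 ± 0.24) and GSTA5 (−3.62 ± 0.22), SST (somatostatin, −3.90 ± 0.12), the chemokine receptor ACKR3 (−3.36 ± 0.30) and the atrial myosin MYL7 (−2.88 ± 0.22) were lower. LAMP5 (−3.18 ± 0.17), ZBED2 (−2.84 ± 0.14), SLITRK6 (−2.83 ± 0.30) and MAMDC2 (−2.77 ± 0.27) were lower too. Adjusted p was at most 0.002 for these genes. IL13RA2, and ASPN on the D21 arrays, were not above background at D0, so their ratios rest on dim D0 signals. POU5F1 (−0.06 ± 0.09), SOX2 (0.08 ± 0.08) and NANOG (0.10 ± 0.12) did not pass, with adjusted p of 0.72, 0.564 and 0.635, while DNMT3B fell further by −0.68 ± 0.10 (adjusted p = 0.00506). AFP was at −2.38 ± 0.75 and did not pass (adjusted p = 0.0756), but did in the paired fit with the letter as a block (adjusted p = 0.0156).

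Of 40 cell cycle genes 33 fell between D21 and D90 and 0 rose, with a median of −0.89, and 36 fell when adjusted over the list alone (adjusted p = 5.06e-12; adjusted p = 0.826 with an estimated correlation). The mitotic kinase CDK1 fell by −1.58 ± 0.18, CDC6 by −1.07 ± 0.16 and AURKA by −0.89 ± 0.08. No other list passed. Of 38 neural genes 12 fell and 0 rose (adjusted p = 0.0637), among them PAX6 (−2.14 ± 0.22) and NES (−1.62 ± 0.14), and of 29 cardiac genes 7 fell and 0 rose (adjusted p = 0.0712), among them TNNT2 (−1.51 ± 0.17) and HAND1 (−1.50 ± 0.13). Of 29 epithelial genes 10 fell and 1 rose (adjusted p = 0.0874), with KRT7 at −2.67 ± 0.29. Adjusted over the list alone, 13 neural, 8 cardiac and 11 epithelial genes fell and 1 epithelial gene rose. Agilent's own ratio called these 3 lists lower (adjusted p of 0.0243 neural, 0.0433 cardiac and 0.0247 epithelial). Of 17162 genes tested, 3746 (21.8%) were called, 1349 higher and 2397 lower, and 713 changed at least 2-fold. The count was 2173 without H1 D21 replicate A, 1943 and 1693 without H13 D21 replicate A or B, and 2310 and 2084 without H13 D90 replicate A or B. Contrasts for each line alone gave 697 calls in H1 and 2924 in H13, and 22 genes were called for a difference between the lines.

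**Figure D2:**
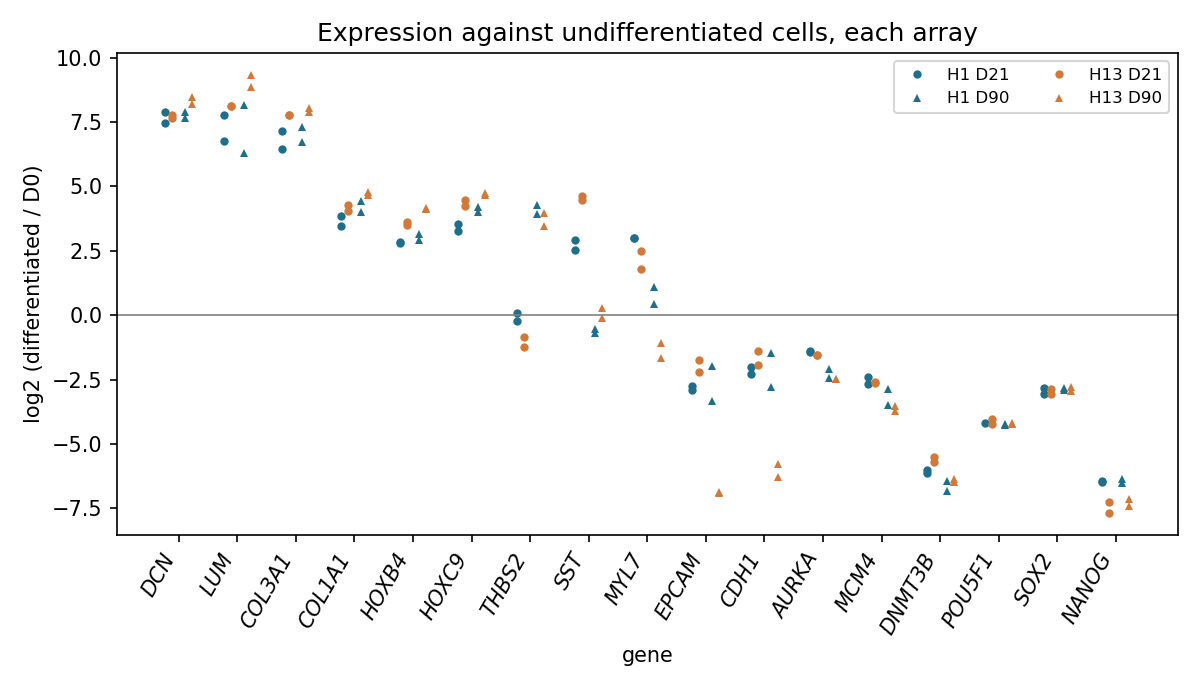
Log2 ratio of differentiated to undifferentiated cells (vertical axis) of 17 genes (horizontal axis), each point 1 array, by line (colour) and stage (circle D21, triangle D90). The genes were chosen after their values were seen. In H1, DCN at D21, COL1A1 at D90 and COL3A1 at both stages are saturated. THBS2 is high on D90 arrays and SST on D21 arrays, and EPCAM and CDH1 are lowest on the H13 D90 arrays, with H13 means of −6.89 and −6.03.

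The comparison of H13 with H1 asks whether the change from D0 differed between the lines. Higher or lower in H13, here and below, means a higher or lower ratio to D0 of the same line. A difference between the lines in D0 levels would give the same value and was not tested. At D21 the imprinted growth regulator gene H19 was higher in H13 by 3.36 ± 0.30, with a mean of 3.60 ± 0.05 in H13 and 0.24 ± 0.06 in H1 (SD, n = 2). GNG4, a G protein subunit, differed by 3.41 ± 0.24 and HTRA1, a secreted protease, by 2.69 ± 0.11. TTC29, a gene of sperm flagella, was lower in H13 by −3.55 ± 0.10, OLFML3, a secreted matrix protein, by −2.72 ± 0.19 and NELL1, a secreted osteogenic protein, by −2.70 ± 0.17. These 6 genes had adjusted p of at most 0.00449. H19 lost its call without H13 replicate B (3.33, adjusted p = 0.0617), and the others kept theirs without any 1 array. In all 1693 of 17171 genes differed at D21, 999 higher and 694 lower in H13, and 452 at least 2-fold. The count was 2587 in the paired fit with the letter as a block, 1710 with line and letter as a random block, and 520, 137, 127 and 34 without H1 replicate A, H1 replicate B, H13 replicate A or H13 replicate B.

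At D21 the cell cycle list was lower in H13, with a median of −0.30 and 0 genes called by limma (adjusted p = 0.00666; adjusted p = 0.752 with an estimated correlation). Of 36 hepatic genes 3 were lower and 1 higher (median −0.26, adjusted p = 0.0159; adjusted p = 0.752 with an estimated correlation). The liver gene APOA1 (−2.10 ± 0.40), FOXA2, an endoderm regulator (−1.62 ± 0.28), and VIL1, an intestinal actin bundler (−1.45 ± 0.24), were the lower ones. Each lost its call without H1 replicate B (adjusted p of 0.0602 to 0.103), H13 replicate A (0.133 to 0.145) or H13 replicate B (0.102 to 0.166), and FOXA2 also without H1 replicate A (0.0837). Of 40 mesenchyme genes 4 were higher and 3 lower (median 0.39, adjusted p = 0.046; adjusted p = 0.752 with an estimated correlation), a call that median centring ended (adjusted p = 0.128). The 23 methylation machinery genes had 1 lower member (median −0.18, adjusted p = 0.046; adjusted p = 0.752 with an estimated correlation), and did not pass in the paired fit with the letter as a block (adjusted p = 0.0576). Adjusted over the list alone, 0 cell cycle genes, 1 hepatic gene higher and 3 lower, 11 mesenchyme genes higher and 3 lower, and 2 methylation machinery genes higher and 7 lower were called. COL1A1 differed by 0.51 ± 0.19 at D21 (adjusted p = 0.146, and 0.0449 with the letter as a block). AFP differed by −3.33 ± 1.07 at D21 (adjusted p = 0.109, and 0.0263 with the block). Between the lines this block can make adjusted p too low, so neither gene is counted as called.

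At D90 several epithelial genes were lower in H13 than in H1. Of the named chemokine genes CCL4 was lower and CXCL1 and CXCL6 were higher, and chemokines were not tested as a list. The chemokine CCL4 differed by −4.83 ± 0.38, the protease MMP7 by −4.82 ± 0.21, the laminin LAMB3 by −4.28 ± 0.22, the adhesion genes EPCAM by −4.25 ± 0.39 and CDH1 (E-cadherin) by −3.90 ± 0.42, VIL1 by −4.02 ± 0.24 and the protease inhibitor A2M by −3.61 ± 0.15. EPCAM stood at −6.89 ± 0.01 in H13 and −2.65 ± 0.97 in H1 (SD, n = 2). Higher in H13 were IL13RA2 (2.86 ± 0.19), H19 (2.79 ± 0.30), GNG4 (2.79 ± 0.24), HTRA1 (2.63 ± 0.11) and the synaptic gene SYT4 (2.88 ± 0.20). These 12 genes had adjusted p of at most 0.00579 and kept their calls without any 1 array. At D0 IL13RA2 was not well above background in either line, nor were MMP7 and A2M in H13, so their values rest on dim D0 signals. The chemokines CXCL1 (3.07 ± 0.41) and CXCL6 (2.34 ± 0.35) and PTX3 (1.97 ± 0.22) were also higher in H13; CXCL1 lost its call without H13 replicate A (adjusted p = 0.0521) and PTX3 without H13 replicate B (adjusted p = 0.0519). Of 29 epithelial genes 6 were lower and 0 higher, 11 lower when adjusted over the list alone, with a median of −1.06 (adjusted p = 3.24e-05; adjusted p = 0.614 with an estimated correlation). Against H1 replicate A alone the median was −0.26 and 15 of 29 genes were lower, and against H1 replicate B alone it was −1.56 and 25 of 29 were lower. The keratins KRT8 (0.27 ± 0.18), KRT18 (0.08 ± 0.28, saturated on 1 H1 array) and KRT7 (0.11 ± 0.41) did not pass.

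The cell cycle list was again lower in H13 at D90, with a median of −0.51 and 0 genes called by limma, also adjusted over the list alone (adjusted p = 3.24e-05; adjusted p = 0.761 with an estimated correlation). Of 23 methylation machinery genes 4 were lower, and adjusted over the list alone 7 lower and 1 higher (median −0.29, adjusted p = 0.00117; adjusted p = 0.614 with an estimated correlation). The 4 were ZBTB38 (−0.78 ± 0.12), MBD1 (−0.56 ± 0.14), UHRF2 (−0.53 ± 0.10) and ZBTB33 (−0.53 ± 0.08), and each lost its call without H13 replicate A (adjusted p of 0.0893 to 0.189) or B (0.0797 to 0.172). MBD1 also lost it without H1 replicate A (0.0764) and UHRF2 without H1 replicate B (0.0576). With the letter as a block the cell cycle inhibitor list (median 0.28) and the TGF-beta list (median 0.26) also passed as higher. Each had adjusted p = 0.0452, against 0.0762 and 0.173, but this block can make adjusted p too low between the lines. In all 2032 genes differed, 1145 higher and 887 lower, and 499 at least 2-fold. The count was 3984 without H1 replicate A (44.1% higher, against 56.3%), and 291 and 225 without H13 replicate A or B. The arrays of each line shared a slide, so line and slide cannot be told apart in these comparisons, except as weighed for the epithelial list at D90 in the part on flagged results.

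The methylation assay at D21 asks which fragments gain or lose methylation as cells differentiate. Of the regions called, CpG-dense ones mostly gained signal. Of 499 called regions with more than 4 CpGs per 100 bases, 476 were higher at D21 (95.4%), against 59.1% of the other called regions (odds ratio 14.3, Fisher's exact test, two-sided, p = 1.07e-58 across regions, which are not independent replicates). Over all regions, called or not, the median was 0.01 with 4 to 6 and −0.004 with over 6 CpGs per 100 bases, and on H13 replicate A −0.04 and −0.09. The largest gain was on chromosome 7 at 27219837 to 27220154, by 2.71 ± 0.25 (SE, n = 4; adjusted p = 0.00408, and 0.0506 without H1 replicate A), and its nearest named region is that of the homeobox gene EVX1, 32320 bp away. Among regions that carry a gene's transcribed sequence, those of SLC11A1, a metal transporter (2.14 ± 0.07, chromosome 2, 218960149 to 218961049), TMEM190 (1.73 ± 0.04), POLD1, a DNA polymerase subunit (1.44 ± 0.11), SEMA6C, a semaphorin (1.44 ± 0.06), and PCDHGC5, a protocadherin (1.16 ± 0.07), gained. Of 465 named regions 29 were higher and 5 lower. Positions are those of the files, which name no genome build.

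**Figure D3:**
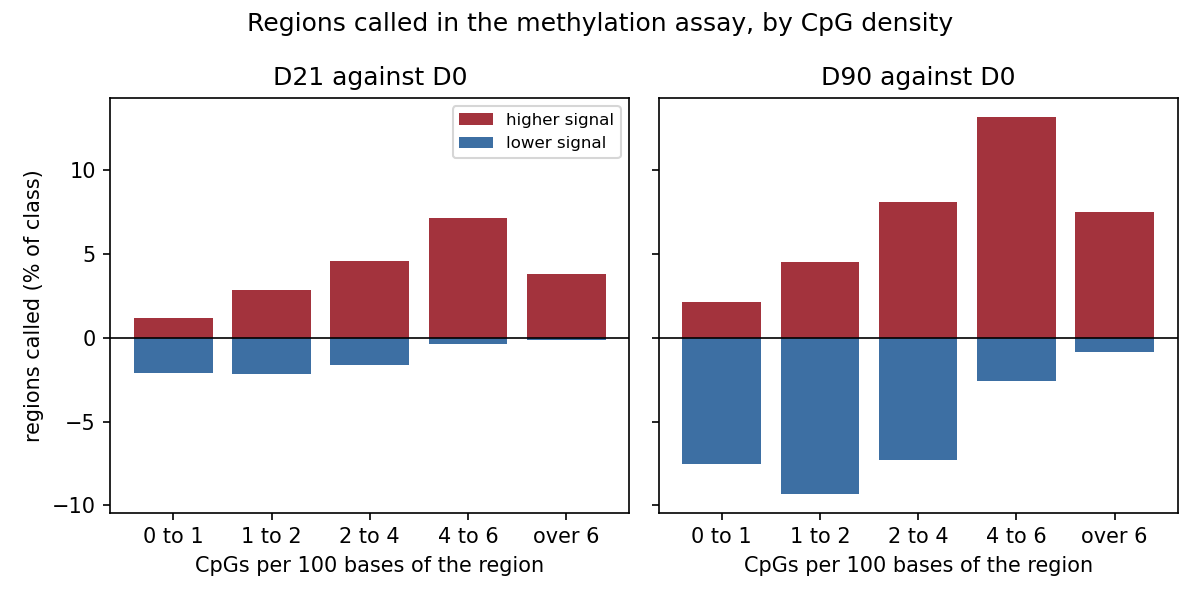
Share of tested regions called in the methylation assay (vertical axis, percent of each class, lower drawn below 0) by CpGs per 100 bases (horizontal axis), at D21 and D90 against D0. Of the regions called with over 6 CpGs per 100 bases, 96.1% are higher at D21 and 89.8% at D90.

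Of 31058 regions 1539 were called at D21, 1091 higher and 448 lower, and 216 changed at least 2-fold. The count was 2493 in the paired fit with the letter as a block, 1318 with line and letter as a random block, and 289, 362, 445 and 344 without H1 replicate A, H1 replicate B, H13 replicate A or H13 replicate B. The lines tested apart gave 575 calls in H1 and 1162 in H13; of 306 called in both 300 moved the same way, while changes of all regions correlated at 0.147. With normexp background correction, which raised the median of all regions by 0.18 at D21 and 0.12 at D90, 91.6% of calls at D21 were higher, against 70.9%. The shares higher at D21 were then 98.2% of called dense regions and 88.3% of the other called regions. With array weights they were 89.6% and 47%.

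Of the regions called at D90, CpG-dense ones again mostly gained and the others mostly lost signal. Of 1045 called dense regions 904 were higher and 141 lower (86.5% higher), and of the others 1061 were higher and 1727 lower (38.1%; odds ratio 10.4, Fisher's exact test, two-sided, p = 2.38e-171). Over all regions, called or not, the median was 0.05 with 4 to 6 and 0.03 with over 6 CpGs per 100 bases, and on H13 replicate A −0.07 and −0.12. It was highest on H1 replicate A, at 0.22 and 0.28, with 0.031 and 0.031 on H1 replicate B and 0.008 and −0.014 on H13 replicate B. With normexp correction the share of higher calls among CpG-poor regions turned to 64.2%, and that among dense regions was 95.6%. The region on chromosome 7 at 27219837 reached 3.36 ± 0.25. The named regions of SLC11A1 (2.59 ± 0.07), CPLX1, a synaptic complexin (1.94 ± 0.16), POLD1 (1.85 ± 0.11), TMEM190 (1.84 ± 0.04), SEMA6C (1.77 ± 0.06), PCDHGC5 (1.55 ± 0.07), SELENOM, a selenoprotein (1.21 ± 0.09), and IDUA, a lysosomal enzyme (1.06 ± 0.10), were higher. That of STRA6, the receptor for retinol-binding protein, was lower by −3.15 ± 0.17 (chromosome 15, 72259125 to 72259532). It averaged −2.18 in H1 and −4.11 in H13. Those of POLD1 (1.40 in H1 and 2.31 in H13) and IDUA (0.51 and 1.62) also changed more in H13. These differences between the lines were not called. The largest loss was on chromosome 19 at 52914134 to 52914318, by −3.43 ± 0.09, which is 23724 bp from the named region of EHD2. Of 465 named regions 47 were higher and 20 lower.

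Of 31058 regions 3833 were called at D90, 1965 higher and 1868 lower, and 577 changed at least 2-fold. The count was 6073 in the paired fit with the letter as a block, 3549 with line and letter as a random block and 1766 without H1 replicate A. Normexp correction gave 75% higher, against 51.3%. Contrasts for each line alone gave 2729 calls in H1 and 3101 in H13, and 1191 of the 1383 called in both moved the same way. D21 and D90 shared 1029 higher and 410 lower regions, and 3 had opposite signs. Independent lists would share 69 and 26.9. Simulated unchanged groups shared 0, which again does not weigh the overlap, since few calls can arise without any change. The changes correlated at 0.815 (simulated 0.523), with a covariance of 0.0534 (simulated 0.00632), and at 0.562 to 0.796 between stages of different letters. The simulated correlation again only returns the value put in, 0.522, and no dye effect was simulated. Of the gene lists, the lineage transcription factors had 8 named regions, of which 1 was called as higher at each stage, and the other lists had at most 3.

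Between D21 and D90, 14 regions lost signal and 1 gained, and none of the 15 carries a gene name. The loss of the region on chromosome 19 at 52914134 deepened by −1.90 ± 0.13 (adjusted p = 0.0255; adjusted p = 0.0892 in the paired fit with the letter as a block), from −1.99 to −2.63 in H1 and from −1.08 to −4.23 in H13, and the region on chromosome 16 at 53530470 gained 1.73 ± 0.10 (adjusted p = 0.0176; adjusted p = 0.0731 with the block). In this chromosome 16 region 2 of 6 H13 spots at D21 were dim in both channels and set to 0, and 0 at D90. The block left 0 regions called by limma, with 2950 at an unadjusted p under 0.05 and 1503 without it, while limma called 131 with line and letter as a random block, among them all 15. The count was 0 without any 1 array, except 5 without H13 D90 replicate B.

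At D21 limma called 0 regions different between H13 and H1, with 4874 at an unadjusted p under 0.05, and 3205 in the paired fit with the letter as a block but 0 with line and letter as a random block. At D90 it called 764, 573 higher and 191 lower in H13. CpG-dense regions were mostly lower in H13 (144 of 183 called) and the others mostly higher (534 of 581; odds ratio 0.024). The named regions of FBXO2, PRTN3, KCNH2 and APOBEC3H were higher and those of FBRS, MC1R and GNAS lower in H13. All 7 lost their call with normexp correction (adjusted p of 0.0707 to 0.224). The count was 4758 with the block, 436 with the random block, 0 without H1 replicate A or without H1 replicate B, and 243 without H13 replicate A. Normexp correction gave 55.9% higher and removal of a trend with GC content 64.7%, against 75%.

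**Figure D4:**
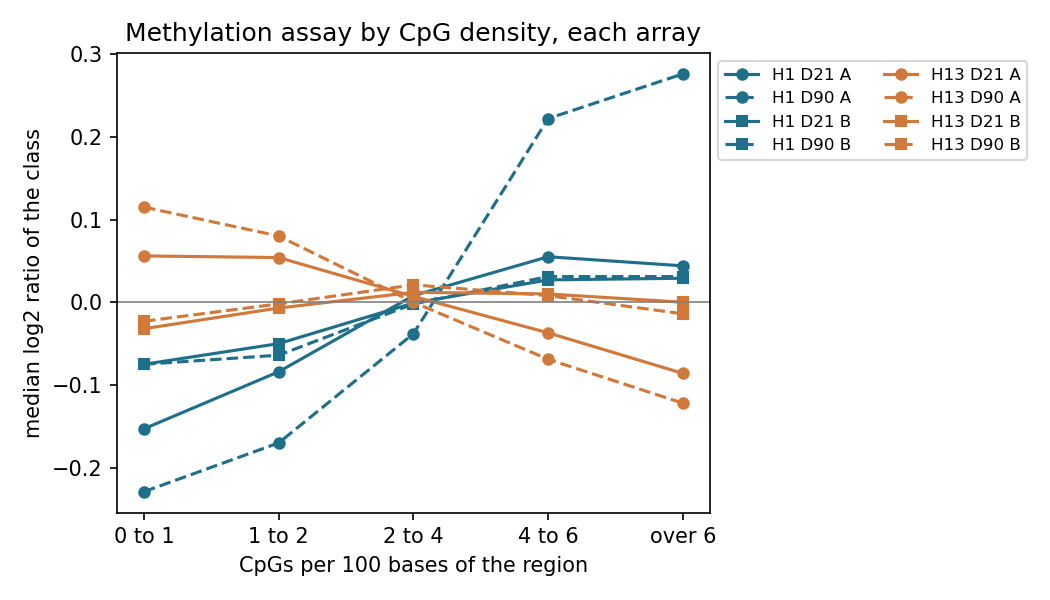
Median log2 ratio of differentiated to undifferentiated cells in the methylation assay (vertical axis) by CpGs per 100 bases of the region (horizontal axis), each line 1 array. H1 D90 replicate A rises from −0.23 in the poorest to 0.28 in the richest class, and H13 D90 replicate A falls from 0.12 to −0.12.

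The join of both assays asks whether methylation and expression changed together. SELENOM gained signal in its transcribed sequence (0.97 ± 0.09 at D21) and rose in expression (3.35 ± 0.05), as did IDUA (0.91 ± 0.10 and 1.94 ± 0.09), TMEM190 (1.73 ± 0.04 and 0.85 ± 0.07) and RIN3, a Ras effector (0.48 ± 0.06 and 1.44 ± 0.08). POLD1 gained signal (1.44 ± 0.11) and fell in expression (−1.47 ± 0.09), as did CPLX1 (1.30 ± 0.16 and −0.47 ± 0.04). At D90 STRA6 lost signal (−3.15 ± 0.17) and rose in expression (2.80 ± 0.05). Its expression had already risen by 2.69 ± 0.05 at D21, when its region stood at −0.85 ± 0.17 and was not called (adjusted p = 0.0557). The regions of IDUA, RIN3 and CPLX1 lost their calls at D21 without any 1 of the 4 arrays, with adjusted p of 0.0527 to 0.0971. Across 456 genes with both values, which are not independent replicates, Spearman's rho was 0.094 at D21 (permutation p = 0.0445, adjusted over 2 correlations 0.089) and 0.062 at D90 (permutation p = 0.182, adjusted 0.182), so neither passed. Of 25 genes called in both assays at D21, 14 rose and 9 fell where methylation gained, and 0 rose and 2 fell where it was lost (Fisher's exact test, two-sided, p = 0.183). Of 52 genes at D90 these counts were 25, 13, 5 and 9 (odds ratio 3.37, Fisher's exact test, two-sided, p = 0.0647). Over the genes called in both assays alone rho was 0.317 at D21 (permutation p = 0.12) and 0.351 at D90 (permutation p = 0.0106), while over all genes at D90 it was 0.071 in H1 (permutation p = 0.13) and 0.006 in H13 (permutation p = 0.894).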

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

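Tests of the D0 and differentiated channels, of a slide effect, of epithelial cells, of undifferentiated cells and of replicate A were chosen only after the result was seen. The genes, lists and regions flagged here differ in the change from D0 between H13 and H1, by a test of that difference; correlations and medians of single arrays are given without one.

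Between the lines 1693 genes differed at D21 and 2032 at D90, and 764 methylation regions at D90. Higher in H13 at D21 were GNG4 (3.41), H19 (3.36), TRBV5-4 (2.81), CD70 (2.79), HTRA1 (2.69), SFRP1 (2.67), EDN1 (2.55), SERPINB2 (2.50), SLC35G2 (2.44) and RPSA (2.40). Lower at D21 were TTC29 (−3.55), COL21A1 (−3.32), FGF18 (−3.24), OLFML3 (−2.72), NELL1 (−2.70), PRPH (−2.69), ANGPTL1 (−2.40), SMIM43 (−2.35), PDE8B (−2.30) and ABCC13 (−2.24). Of these 20 genes 8 kept their call without any 1 array. Higher in H13 at D90 were CXCL1 (3.07), SYT4 (2.88), IL13RA2 (2.86), H19 (2.79), GNG4 (2.79), PPP1R3C (2.70), HTRA1 (2.63), B3GAT1 (2.55), CRHBP (2.40) and RARRES2 (2.36). Lower at D90 were CCL4 (−4.83), MMP7 (−4.82), LAMB3 (−4.28), EPCAM (−4.25), VIL1 (−4.02), LTB (−3.98), CDH1 (−3.90), A2M (−3.61), UBD (−3.39) and S100A14 (−3.33), and 16 of the 20 genes at D90 kept their call without any 1 array.

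Genes named for their change with stage also differed between the lines. At D21 these were LOX (0.72), NANOG (−1.01), CFAP95 (−1.17), THBS2 (−0.99), ASPN (−2.18), SST (1.81), LAMP5 (−1.19) and ZBED2 (1.20). At D90 they were LOX (0.74), CDH11 (1.61), ITGA11 (1.38, with a value on 1 of the 2 H1 arrays, so that its spread comes from the other groups), NANOG (−0.82), CFAP95 (−0.90), PTX3 (1.97), ALDH1A1 (1.98), CXCL6 (2.34), SMOC2 (1.501), SST (0.71), LAMP5 (−1.45) and MYL7 (−2.12). At D21 LOX, NANOG, THBS2, ASPN and LAMP5 lost their call without each of the 4 arrays in turn, ZBED2 without 3 of them, and CFAP95 and SST without H13 replicate B. At D90 CFAP95 and CXCL6 kept their call without any 1 array, and SST lost its call in the paired fit with the letter as a block (adjusted p = 0.0593). At D0 ANGPTL1 and ASPN on the D21 arrays and IL13RA2 on the D90 arrays were not well above background in either line, nor were RPSA in H1 at D21 and MMP7, A2M and SST in H13 at D90, so these values rest on dim D0 signals. The medians of the called lists were −0.26 for hepatic, 0.39 for mesenchyme, −0.18 for methylation machinery and −0.30 for cell cycle genes at D21, each with adjusted p = 0.752 with an estimated correlation. The mesenchyme call ended with median centring (adjusted p = 0.128) and that of the methylation machinery in the paired fit with the letter as a block (adjusted p = 0.0576). At D90 they were −1.06 for epithelial, −0.29 for methylation machinery and −0.51 for cell cycle genes, with adjusted p of 0.614, 0.614 and 0.761 with an estimated correlation.

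The methylation regions with the largest differences at D90 are given by chromosome and start. Higher in H13 were chromosome 19 at 43487461 (2.67), 2 at 85846493 (2.33, with all H1 spots dim in both channels and set to 0, so nothing was measured in H1), 7 at 7436038 (2.27), 16 at 31052918 (2.19), 17 at 10244377 (2.06), 16 at 3185218 (1.96), 6 at 26925798 (1.95), 22 at 19952316 (1.88), 19 at 436402 (1.85) and 7 at 65847649 (1.84). Lower were chromosome 20 at 3093492 (−3.50), 1 at 53697591 (−2.86), 4 at 162417461 (−2.67), 2 at 91237457 (−2.49), 19 at 18141104 (−2.41), 1 at 33289347 (−2.38), 17 at 18516669 (−2.36), 21 at 35086194 (−2.34), 4 at 9392230 (−2.33) and 17 at 15593534 (−2.31). On the H1 arrays at D90, 2 of 6 spots of chromosome 1 at 53697591 and of 21 at 35086194 were dim in both channels and set to 0. Of the regions with the largest changes by stage, those also lower in H13 were chromosome 16 at 83973361 (−1.70), 19 at 52914134 (−1.61), 17 at 3644810 (−1.21), 12 at 103586585 (−0.93) and 9 at 136738477 (−0.75). Each of these 25 regions lost its call without at least 1 array.

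The epithelial list was lower in H13 than in H1 at D90, with 6 of 29 genes called, and did not pass with an estimated correlation (adjusted p = 0.614). A slide effect alike on all arrays of a line is argued against by D21, where the list's median on the same slides was 0.084 (bootstrap −0.098 to 0.494), and the within-array normalization by a median of −1.17 or lower with median centring and with Agilent's own ratio. More undifferentiated cells in the H1 cultures are argued against by a pluripotency median of −0.005 (−0.107 to 0.061). Both bootstrap intervals come from resampling the genes of a list, not the arrays. They leave out the spread between the 2 arrays per line and the correlation between genes, so both arguments are weaker than the intervals make them look. More epithelial cells in the H1 cultures may contribute and stay open, since 5 of 8 simple-epithelium genes were lower in H13, with EPCAM, CDH1 and CLDN4 called, while KRT8 and KRT7 were not lower and KRT18 was saturated on 1 H1 array. An effect of 1 array cannot be told apart with 2 arrays per line: the list medians were 0.43 and 1.52 on the H1 arrays and 0.205 and 0.148 on the H13 arrays, and the lower H1 median lay 0.229 above the higher H13 one.

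The difference between the lines in methylation at D90 ran with CpG density. A single array as the cause is argued against by Spearman correlations of −0.53 to −0.285 over the 4 fits without 1 array (−0.43 with all). Most of it lay between the A arrays (−0.523) and little between the B arrays (−0.09), so something confined to replicate A of both lines may account for it. A difference in methylation between CpG-dense and CpG-poor regions cannot be told apart from that, since the correlation among 11879 regions of 50 to 60% GC was −0.319, with −0.358 between the A and −0.07 between the B arrays. Nor can a trend with GC content in the amplification be told apart, because the slope among 7946 regions with at most 1 CpG per 100 bases (−0.00852 ± 0.000675 per percent GC) lay close to the bound of −0.00818 set from the slope over all regions (−0.0164). A gradient of the same direction was present at D21, where 0 regions were called. The median difference there was 0.118 in the poorest and −0.086 in the densest class. The D21 ratios correlated with CpG density at 0.472 in H1 and −0.222 in H13 on the A arrays, and at 0.253 and 0.163 on the B arrays.

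The methylation ratios of the D21 and D90 arrays that share a line and a letter deviated together. Differentiated cultures that differ alike at both stages are argued against by correlations of the Cy5 differences of −0.091 and −0.01. A trend with GC content as the whole cause is argued against by correlations of 0.499 and 0.604 once it was removed (0.558 and 0.668 before). D0 DNA or its preparation shared by the arrays of 1 letter may account for it, since the Cy3 differences correlated at 0.362 and 0.887, and the labels do not state whether D0 samples were shared.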

How the results depend on the processing

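Removing a GC trend, treating spots dim in both channels as missing, and the list tests with median centring or quantile normalization were chosen only after the result was seen. Of 5016 values of 322 named gene results under the alternatives 4791 kept direction and call, 204 lost the call, 19 gained it and 2 reversed, both for MBD2 (0.92 at D21 and 0.88 at D90 with gene means over all probes); of 1937 values of 127 named region results these numbers were 1527, 396, 14 and 0. Spots well above background, 49.3% to 62% in the differentiated channel of the methylation arrays, limit what could be tested there.

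At least a 2-fold change left 4502 genes at D21, 5119 at D90, 713 in D90 against D21, and 452 and 499 in H13 against H1 at D21 and D90; it left 216, 577 and 310 regions at D21, D90 and H13 against H1 at D90. In H13 against H1 at D21 Agilent's ratio gave 628 genes, the deposited ratios 630 and no offset 1016; at D90 Agilent's ratio gave 1057 and the deposited ratios 1066. Array weights gave 2929 and 1171 genes in these contrasts, and 3680, 2340, 8, 1185 and 0 regions in the 5 methylation contrasts. Single probes gave 8515 at D21, 18601 at D90, 6 in D90 against D21 and 2683 in H13 against H1 at D90. For D90 against D21, normexp gave 0 regions (limma, 1258 at an unadjusted p under 0.05), no filter 2 and a random block 131. For H13 against H1 at D21, at least 3 probes gave 60, no filter 22 and GC trend removal 3; at D90 normexp gave 111, no filter 463, a random block 436 and GC trend removal 450.

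The paired fit with the replicate letter as a block gave 2587 genes in H13 against H1 at D21, and 2493, 6073, 0, 3205 and 4758 regions in the 5 methylation contrasts; it changed no call of a list, named gene or named region other than those given in the report and among the flagged results, COL1A1 in H13 against H1 at D90 (adjusted p = 0.0416, saturated in H1), the regions of CDX2 (adjusted p = 0.061, against 0.042) and ICAM5 (adjusted p = 0.0272, against 0.18) at D21, and the regions named in D90 against D21. Methylation and expression correlated at 0.317 and 0.351 over genes called in both at D21 and D90, and at D21 at 0.063 in H13 alone and 0.064 in H1 alone. With an estimated correlation 0 list tests passed. The cause of these changes was not tested.

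Without 1 array, counts ranged from 11431 to 11866 genes at D21, 12279 to 13149 at D90, 1693 to 4604 in D90 against D21, 34 to 520 in H13 against H1 at D21 and 225 to 3984 at D90. For regions they ranged from 289 to 445, 1766 to 4699, 0 to 5, 0 to 0 and 0 to 889 in the same order. A lone array left in a group is assumed to vary like the others. Promoter regions alone were not run, since the files give no promoters.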

Other observations

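No test in this part was chosen after the result was seen. Between D21 and D90 the pluripotency list, which did not pass as a whole (adjusted p = 0.362), had 13 members that fell and 1 that rose of 38, and 14 and 1 adjusted over the list alone. ZFP42 fell by −1.94 ± 0.19 and LIN28B, a blocker of let-7 processing, by −1.69 ± 0.08, while the growth factor FGF2 rose by 2.00 ± 0.07. Of 40 mesenchyme genes 9 rose and 6 fell (adjusted p = 0.246; 10 and 6 adjusted over the list alone), with the matrix gene OGN at 2.55 ± 0.27 and the smooth muscle gene CNN1 at −1.65 ± 0.14. Of 35 HOX genes 5 rose and 4 fell (adjusted p = 0.481; 6 and 4 adjusted over the list alone), with HOXA4 at 1.43 ± 0.19 and HOXA13 at −1.09 ± 0.12. At D0 OGN was well above background on 0 of 8 arrays, HOXA4 on 6 and HOXA13 on 3, so their ratios rest on dim D0 signals.

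Other groupings of the same arrays were tried, with other fits than in the report: the sign changes use the 4 arrays of a stage with 1 mean, the splits use 2 groups without the line, and both use only genes or regions with a value on every array. The counts therefore differ from those of the report. For D21 and D90 against D0 the 8 sign changes are too few for a share under 0.05. The real ones gave 11512 and 11359 genes and 557 and 797 regions, and the highest other gave 0 in each case, so 1 of 8 gave as many each time. For D90 against D21, 2 of 35 splits, the real one (1431 genes) included, gave as many genes as the real one, so chance was not excluded. The other was the split by line, a factor of the design, which gave 1938. The 8 splits that part the pairs gave at most 0 besides the real one. For regions 3 of 35 splits, the real one included, gave as many as the real one (2), and the split by line gave 5347, which points to a structure of the arrays by line.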
